A study of Mus musculus with 49 samples.

How the data were processed

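Single-cell Hi-C was made from 2 mouse ES lines, a diploid F1 hybrid and the haploid H129-1, grown in 2i without feeders or with fetal bovine serum on feeders, where feeder cells were depleted and Oct-3/4-positive cells sorted. Cells were fixed with formaldehyde, and some were sorted on Hoechst and Geminin. Per the labels, reads were aligned with Bowtie2 to mm9. The 4 nuclear RNA samples were not analysed here.

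The deposited data used are 3 tables of cells by features (diploid 2i, diploid serum, haploid) and a list that pairs each cell with its sample. Contacts per cell are a count, per the file headers. The deposited shares (contacts in the near band, in the mitotic band and between chromosomes, without digestion, and of duplicated fragment ends) are each a fraction of a cell's total, shown here in percent, and the limits of the bands and the denominators are not stated. Each deposited score (compartments in cis and in trans, insulation, replication, alignment, chromosome coverage deviation) has a scale that is not defined. The replication score is set so that its lowest cell in each table is 1. The deposited loop enrichments are read as log2 values from their range, and were used for the haploid and diploid 2i tables. Other deposited columns are the distance of far contacts in bp (shown in Mb) and the authors' order, group, condition, quality flag and batch number.

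Only cells that passed the authors' quality control entered the comparisons. Batch numbers were joined to samples through the numbers in the cell list, except diploid 27, which was joined by the number in its title, and a library is a GEO sample within a table. Most values are means over cells of a phase within a library with at least 10 such cells, then mean and SD over libraries. Phase changes were differences between successive phases within a library, tested by a two-sided sign-flip test, exact for under 10 libraries and otherwise with 100000 resamples, with Benjamini-Hochberg correction over 86 tests. Group comparisons took the difference of library means within each phase, averaged it over phases with equal weight, and permuted library labels (exact where a group had under 10 libraries, otherwise 100000 resamples), with correction over the features of a comparison. Scores were tested within a table only. Composition was tested on 1 share per library and side by permuting library labels, with the values of a library on both sides swapped, and pooled shares have exact Clopper-Pearson 95% intervals. For a count of 0 the upper limit is 3 cells over the total. Relations used Spearman's rho in libraries with at least 20 cells of a phase, for 5 feature pairs. Cells were also averaged in 20 bins along the authors' order.

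Added after the data were seen were the minimum of 1 cell, the exclusion of NoSort libraries, haploid 2i libraries alone, libraries holding the 3 phases, the shared lane, leaving out the library with both media, other sets of libraries for differences in phase changes, and the haploid serum comparison. No gene was to be named, since the tables hold no values per gene. The rule for named items was to report every feature for phase changes and, for other comparisons, at most the 10 with the largest difference in SD units past an adjusted p of 0.05, with the others summarised. Cell type markers did not apply. Chromosome copy number was to use limits of 1.3 and 0.7 on each chromosome's share. With the tables used here, the largest coverage deviation per cell at 1 or more replaced it.

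Alternatives were minimums of 5, 20 and 1 cells, medians, all cells pooled, cells within the 25th to 75th percentile of contacts or of overlapping depth, cells whatever their phase, leave-one-out, a replicate block by library number, libraries only whose names give no sort, Pearson and partial correlation, and a minimum of 40 cells for relations. Contacts per cell had a median of 205511 in 2i, 255605 in serum and 80858 in haploid cells, and the number of libraries, from 4 to 17 per group, limits the precision.

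Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The phase test was tested on simulated data of 8 libraries of 40 cells. Of 150 changed features among 300, 98.7% were called, and 4.67% of the unchanged ones. The group comparison, simulated with 8 against 18 libraries, called 100.0% of 30 changed features among 60 and 3.33% of the unchanged ones.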

Results

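Contacts between chromosome segments were measured by Hi-C in single mouse embryonic stem (ES) cells, and each cell was placed along the cell cycle by the authors. Of 5871 cells listed, 4098 passed the authors' quality control. There were 45 Hi-C libraries, 44 of them with passing cells, 25 of a diploid F1 hybrid line and 20 of the haploid line H129-1. The cells fall into 3 groups. Diploid cells grown in 2i, a serum-free medium with inhibitors of differentiation, gave 1992 passing cells in 18 libraries. Diploid cells grown with serum on feeder cells gave 859 in 8 libraries, and haploid cells from either medium gave 1247 in 19 of 20 libraries. The library diploid 2_14 held cells from both diploid groups. In the cell list, no sequencing lane held more than 1 library, so lane and library cannot be told apart, and that library alone sets both media side by side in a lane. The question is how chromosome folding changes through the cell cycle, by the title of the series.

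Depth differed between the groups. A diploid 2i cell had a median of 205511 contacts (25th to 75th percentile 106460 to 299290), a diploid serum cell 255605 (136610 to 388066) and a haploid cell 80858 (49234 to 158676). Summed over its passing cells, a library held between 1452452 and 50126513 contacts in 2i, between 4010537 and 46267744 in serum, and between 332107 and 27496872 in haploid cells. Between 4 and 162 cells passed per library within a table. The library was the unit of every test that gave a p-value, and these tests were two-sided. The labels do not say whether libraries came from separate cultures, so the p-values measure only the spread between these libraries. Binomial intervals and limits for counts of 0 cover counting error only.

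The authors' groups were post-M, G1, early-S, late-S/G2 and pre-M. They separate largely on the share of contacts in a near band of distances, called here the short-range share, and the share in a band named mitotic. The limits of these bands are not stated. In haploid cells, for example, the short-range share spanned 37.9% to 64.1% in G1, 57.5% to 79.5% in early-S and 73.4% to 90.4% in late-S/G2. Changes of these shares between groups are therefore not independent of the grouping. Whether other features entered the grouping or the order is not stated, so their changes and courses along the order are not shown to be independent of it either. Of 86 phase changes tested by sign flips with at least 10 cells per library and phase, 51 passed a Benjamini-Hochberg adjusted p of 0.05. The 51 include every tested change of both band shares, which can also lower the adjusted p of other features.

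From G1 to early S, cells gained short-range contacts, compartment contrast within chromosomes and contacts between chromosomes. The short-range share rose from 54.0% ± 0.941 to 68.1% ± 2.37 (SD, n = 9) in haploid libraries, from 57.1% ± 1.14 to 70.4% ± 2.61 (n = 10) in diploid 2i libraries and from 53.3% ± 1.90 to 71.8% ± 1.11 (n = 7) in serum libraries. The mitotic-band share fell in every library, from 16.6% to 12.3% in haploid, from 16.2% to 12.1% in 2i and from 17.9% to 11.8% in serum libraries. The authors' replication score, whose definition is not given and whose lowest cell is 1 in each table, rose from 1.11 ± 0.0337 to 1.21 ± 0.0418 in haploid, from 1.08 ± 0.0251 to 1.17 ± 0.0460 in 2i and from 1.04 ± 0.0127 to 1.18 ± 0.0283 in serum libraries. The size of this rise varied with condition, 0.157 in serum and 0.0609 in 2i libraries of the haploid line, and 0.0154 in the G1 gate, 0.0737 in the condition 1CDU and 0.125 in the condition NoSort of the diploid 2i table. Of the haploid 2i libraries at this step, 4 were named 2i_G1 and 1 was named 2i_all, so medium and sort are not told apart. Compartment contrast within chromosomes, given by the cis compartment score, rose from 0.286 to 0.370, from 0.339 to 0.411 and from 0.0968 to 0.125 in the same order. All these changes had one direction in every library, with an exact adjusted p of 0.012 in haploid libraries, a permutation adjusted p of 0.012 in 2i libraries and an exact adjusted p of 0.0280 in serum libraries. The smallest p that the sign flips allow is 0.00391 for 9 libraries and 0.0156 for 7. Because these serum changes sit at this floor, each of them lost its place past the threshold when any 1 of the 7 libraries, diploid 2_14, 3, 4, 5_10, 7, 8 or 9, was left out (exact adjusted p from 0.0507 to 0.0527), with directions kept. The short-range rise in serum, for example, then lay between 18.2 and 18.9 points.

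Other features moved in some groups of libraries at this step. Compartment contrast between chromosomes, given by the trans compartment score, rose from 0.153 to 0.240 in haploid and from 0.222 to 0.307 in 2i libraries, in every library (adjusted p = 0.012 by exact and permutation tests). In serum libraries it was higher in 6 of 7 (0.0169 against 0.0345) without passing (exact adjusted p = 0.0507). The share of contacts between chromosomes rose from 6.58% ± 1.64 to 8.61% ± 2.37 in 9 of 9 haploid libraries (exact adjusted p = 0.012), from 5.93% to 6.97% in 9 of 10 diploid 2i libraries (permutation adjusted p = 0.0274, by 0.251 points in NoSort, 1.41 in G1-gate and 1.64 in 1CDU libraries) and from 5.47% ± 0.477 to 7.65% ± 0.442 in 7 of 7 serum libraries (exact adjusted p = 0.0280). The mean distance of far contacts rose from 27.7 to 30.3 Mb in 8 of 9 haploid libraries (exact adjusted p = 0.0217) and from 23.4 to 25.6 Mb in 7 of 7 serum libraries (exact adjusted p = 0.0280). In 2i libraries it was 1.04 Mb longer, in 6 of 10 libraries, without passing (permutation adjusted p = 0.368). This mean joins opposite changes, longer in 4 of 4 libraries of 1CDU (2.77 Mb) and 2 of 2 of the G1 gate (3.99 Mb) and shorter in 4 of 4 named NoSort (-2.16 Mb), a split that was not tested. The authors' alignment score between chromosomes fell from 0.292 to 0.229 in 9 of 9 haploid libraries (exact adjusted p = 0.012) and from 0.324 to 0.289 in 7 of 7 serum libraries (exact adjusted p = 0.0280). It changed by -0.00957 on average in 2i libraries (permutation adjusted p = 0.721), where it fell in 4 of 4 1CDU (-0.0529) and 2 of 2 G1-gate libraries (-0.0508) and rose in 3 of 4 NoSort libraries (0.0543). These serum changes too stopped passing when any 1 of the 7 libraries was left out. Mean insulation differed by -0.0105, -0.00288 and 0.0121 in haploid, 2i and serum libraries (adjusted p = 0.758, 0.919 and 0.604 by exact and permutation tests). These means join changes of either sign. Among haploid libraries, insulation fell in 4 of 4 grown with serum (-0.0883 ± 0.0363, SD) and rose in 4 of 5 grown in 2i (0.0518 ± 0.0377), a difference of -0.140 that did not pass (exact p = 0.0159, adjusted p = 0.0529 over 40 tests of this kind). As above, medium and sort are not told apart here. Among diploid 2i libraries, insulation rose in 4 of 4 of 1CDU (0.0246) and 2 of 2 of the G1 gate (0.107) and fell in 4 of 4 NoSort libraries (-0.0851), also untested. Diploid serum libraries rose in 4 of 7. The sign of the mean turned without haploid 20 (0.00561), and in 2i libraries without diploid 28_29, 30_31 or 32_33 (0.00933, 0.00613 and 0.0102). Contacts per cell rose from 91172 to 114048 in 7 of 9 haploid libraries (exact adjusted p = 0.0395), mostly in serum, with 46685 more in 4 of 4 serum libraries against 3827 more on average in 2i, higher in 3 of 5 (exact adjusted p of the difference = 0.0318 over 40 tests). That rise stopped passing without haploid 7, 12, 13, 17, 18, 19 or 20, with values from 16725 without haploid 20 to 25019 without haploid 7. As for insulation, medium and sort are not told apart. In 2i libraries contacts did not pass (13497 more, permutation adjusted p = 0.0648), but did without diploid 19 (16780 more, adjusted p = 0.0280). The serum change did not pass (13580 more, exact adjusted p = 0.331). Of the quality measures, the duplicated share rose from 0.940% to 1.22% in 8 of 9 haploid and from 2.70% to 3.01% in 7 of 7 serum libraries (exact adjusted p = 0.0280 each), coverage deviation fell from 0.388 to 0.353 in 9 of 9 haploid libraries (exact adjusted p = 0.012) and from 0.364 to 0.340 in 8 of 10 diploid 2i libraries (permutation adjusted p = 0.0336), and the share without digestion did not pass in any group. Leaving out libraries was not tried for these quality measures.

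**Figure D1:**
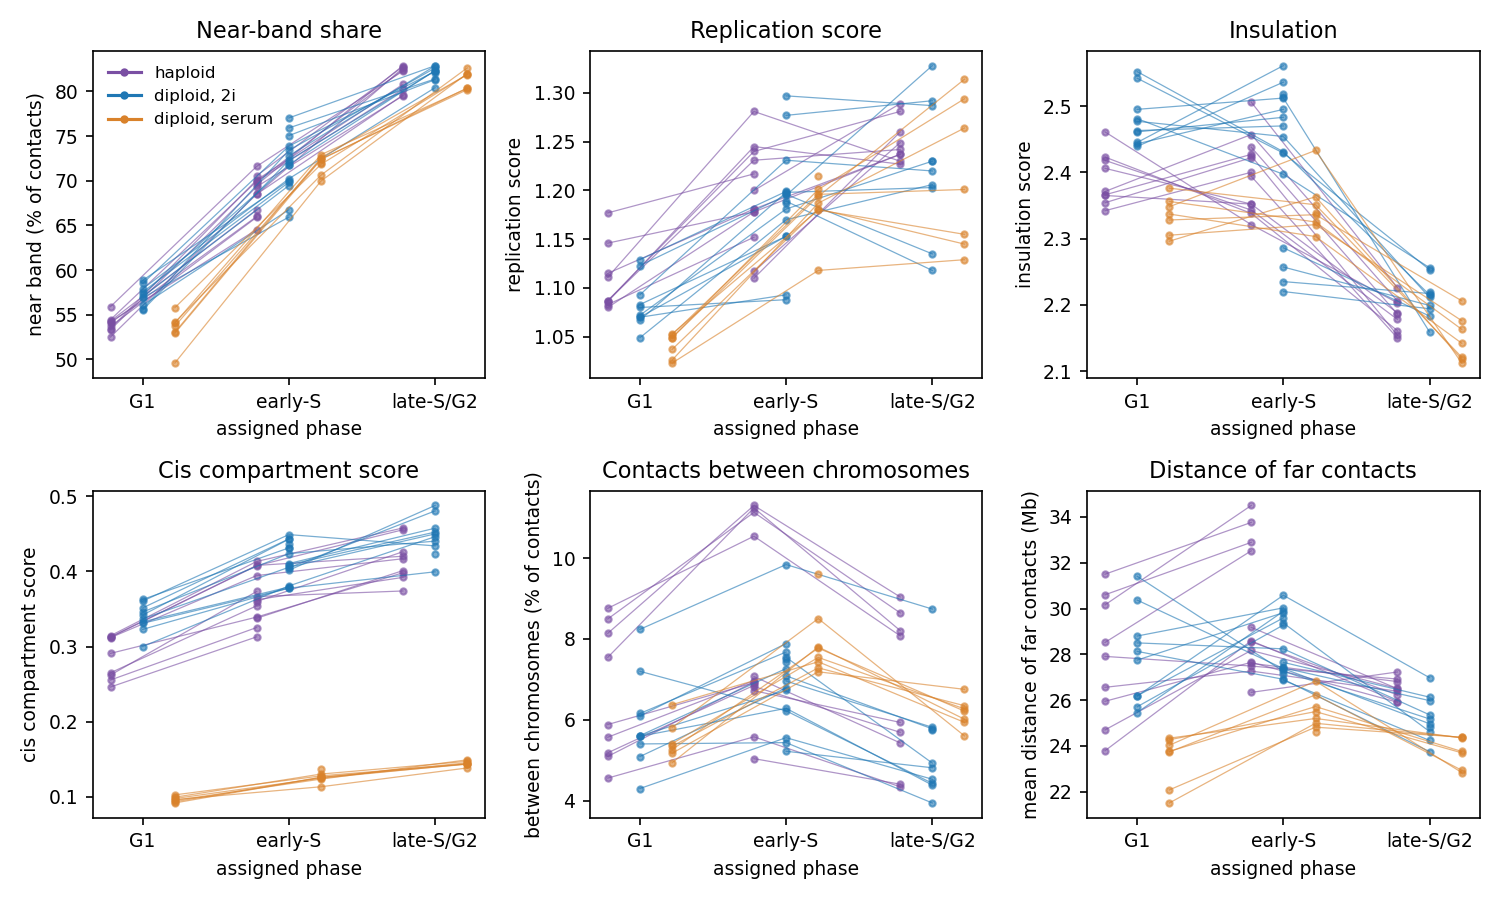
Short-range (near-band) share, replication score, insulation, cis compartment score, share of contacts between chromosomes and far distance by assigned phase, where each point is a library's mean over at least 10 cells, lines join the phases of a library and colours give the group. Insulation is lower in late S/G2 than in early S in every joined library, and the serum compartment scores, possibly on another scale, lie between 0.0920 and 0.149.

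From early S to late S/G2, domain insulation fell in every library of every group. It went from 2.40 ± 0.0633 to 2.18 ± 0.0256 (SD, n = 9, exact adjusted p = 0.012) in haploid libraries, from 2.36 ± 0.109 to 2.21 ± 0.0313 (n = 9, exact adjusted p = 0.012) in 2i libraries and from 2.35 ± 0.0425 to 2.15 ± 0.0352 (n = 7, exact adjusted p = 0.0280) in serum libraries. In the diploid 2i table the size of the fall varied with the sort, -0.0218 in 2 libraries of the mid-S gate, -0.0807 in 2 of the late gate, -0.194 in 4 NoSort libraries and -0.353 in 1 1CDU library, differences that were not tested. The short-range share rose further, by 11.7, 8.45 and 9.51 percentage points, and the mitotic-band share fell from 11.9% to 8.27%, from 11.3% to 8.33% and from 11.8% to 8.69% in haploid, 2i and serum libraries, in every library. Contacts between chromosomes turned down at this step. Their share fell from 8.38% to 6.64% in haploid, from 6.68% to 5.26% in 2i and from 7.65% to 6.16% in serum libraries, in every library. Compartment contrast kept rising within chromosomes, from 0.377 to 0.416 in 9 of 9 haploid, from 0.407 to 0.450 in 8 of 9 diploid 2i (exact adjusted p = 0.0217, lower in the 1 1CDU library) and from 0.125 to 0.145 in 7 of 7 serum libraries.

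Far contacts drew in at the same step. The mean distance fell by 2.72 Mb in 9 of 9 diploid 2i libraries (exact adjusted p = 0.012), from 25.6 to 23.8 Mb in 7 of 7 serum libraries (exact adjusted p = 0.0280, -0.491 Mb with 1CDS1 and -3.135 Mb with 1CDS2 cells) and from 27.9 to 26.5 Mb in 8 of 9 haploid libraries (exact adjusted p = 0.0336). The haploid fall stopped passing without haploid 3, 6, 7, 8, 17, 18, 19 or 20, with values from -1.22 Mb without haploid 3 to -1.48 Mb without haploid 17. As at the step before, each serum change stopped passing when any 1 of its 7 libraries was left out, the insulation change then lying between -0.211 and -0.179. Between chromosomes, compartment contrast rose by 0.0436 in haploid and 0.0331 in 2i libraries, in every library (exact adjusted p = 0.012). In diploid 2i cells within the 25th to 75th percentile of contacts, the rise was 0.00851 over 6 libraries and did not pass (exact adjusted p = 0.726), so it is not shown apart from depth. By sort it was 0.0161 in NoSort, 0.0387 in mid-S-gate and 0.0730 in late-gate libraries. The serum difference of 0.00455 did not pass (exact adjusted p = 0.130). In 2i libraries the alignment score rose from 0.247 to 0.302 and contacts per cell from 183670 to 221564, in 9 of 9 libraries each (exact adjusted p = 0.012). Neither passed in haploid or serum libraries, although haploid contacts did without haploid 18 (18494 more, exact adjusted p = 0.0210). The haploid alignment change of -0.00183 turned positive without haploid 1, 17 or 6 (0.00376, 0.000897 and 0.00342). The replication score did not pass in any group (0.0521, 0.00950 and 0.0349 higher on average, exact adjusted p = 0.0811, 0.758 and 0.265). Conditions differed here. In haploid cells it rose by 0.0974 in 5 of 5 2i libraries and changed by -0.00454 in serum, higher in 2 of 4. In diploid 2i cells the mean change was 0.0198 over 4 NoSort libraries (higher in 3), 0.00248 over 2 of the mid-S gate (higher in 1), 0.133 in 1 1CDU library and -0.0661 over 2 of the late gate (lower in both). Diploid serum cells showed a rise of 0.0945 in 4 of 4 libraries with 1CDS1 cells, and a fall of 0.0137 on average, in 3 of 4, with 1CDS2 cells. In haploid libraries it passed without haploid 19 (0.0650, exact adjusted p = 0.0403), and in 2i libraries it turned to -0.00600 without diploid 11. Of the quality measures, only the duplicated share in 2i libraries passed, rising from 3.79% to 4.24% in 9 of 9 (exact adjusted p = 0.012).

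Loop enrichments, given on a log2 scale for loops that the tables call EE and LL without further definition, were listed for haploid and diploid 2i cells. From early S to late S/G2, LL enrichment fell from 0.96 to 0.72 in 8 of 9 diploid 2i libraries (exact adjusted p = 0.0217, -0.30 in NoSort, -0.10 in late-gate and -0.07 in mid-S-gate libraries) and EE enrichment fell from 1.02 to 0.94 in 8 of 9 haploid libraries (exact adjusted p = 0.0280). The LL change in haploid libraries was -0.05 (exact adjusted p = 0.462) and the EE change in 2i libraries -0.02 (exact adjusted p = 0.760), lower in 3 of 4 NoSort and higher in 2 of 2 late-gate libraries. From G1 to early S no loop enrichment passed. Whether the changes differ between haploid and 2i libraries was not tested.

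Cells next to mitosis reached the minimum of 10 in 1 library, diploid 26 with 15 pre-M cells, where the mitotic-band share was 15.3 points higher and the far distance shorter (24.2 to 15.0 Mb) than in late-S/G2. No test can be made on 1 library, so values with at least 1 cell per library and phase were computed after the data had been seen and adjusted over 172 tests. From late S/G2 to pre-M in haploid libraries, contacts shifted into the mitotic band (13.7 percentage points more than 8.28% ± 0.440, SD, n = 9), the far distance shortened from 26.2 to 16.7 Mb, the share between chromosomes fell from 6.64% to 2.47%, and the replication score fell from 1.24 to 1.08, each in 9 of 9 libraries (exact adjusted p = 0.0175). Insulation fell from 2.18 to 2.04 in 8 of 9 (exact adjusted p = 0.0240). From post-M to G1 in 7 diploid 2i libraries, insulation rose from 1.68 ± 0.0551 to 2.45 ± 0.0996, the far distance lengthened from 11.7 to 25.6 Mb and the mitotic-band share fell from 41.3% to 18.4%, in every library (exact adjusted p = 0.0390). The fall of this share was fixed by the grouping, with post-M cells at 31.64% or more and G1 cells at 31.48% or less. Its rise into pre-M was largely set by the grouping too, as the 21 haploid pre-M cells lay at 9.832% or more. Of the 29 post-M cells, 17 came from the late S/G2 sort gate described below, and 0 of 280 G1-gate cells were post-M. The place of post-M before G1 thus rests on the authors' assignment and not on the gates. Entry into pre-M in 6 diploid 2i libraries went the same way as in haploid libraries for the mitotic-band share (8.30% to 18.7%) and the far distance (25.5 to 15.6 Mb) without passing (exact adjusted p = 0.0664). With 4 serum libraries no exact p below 0.125 is possible.

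Along the authors' order of cells in 20 bins of equal size, replication and insulation ran out of step. The replication score was highest in bin 14 of the 2i table (1.34), bin 13 of the serum table (1.31) and bin 15 of the haploid table (1.37). Insulation was highest earlier, in bins 7, 5 and 7 (2.58, 2.44 and 2.46), and had fallen to 2.25, 2.18 and 2.20 where replication peaked. Its lowest values were in bin 20 (2.13, 2.08 and 2.11), and bin 1 was also low (2.13, 2.13 and 2.28). Contacts between chromosomes were highest in bins 10, 6 and 12. These bins pool cells over libraries and carry no test.

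**Figure D2:**
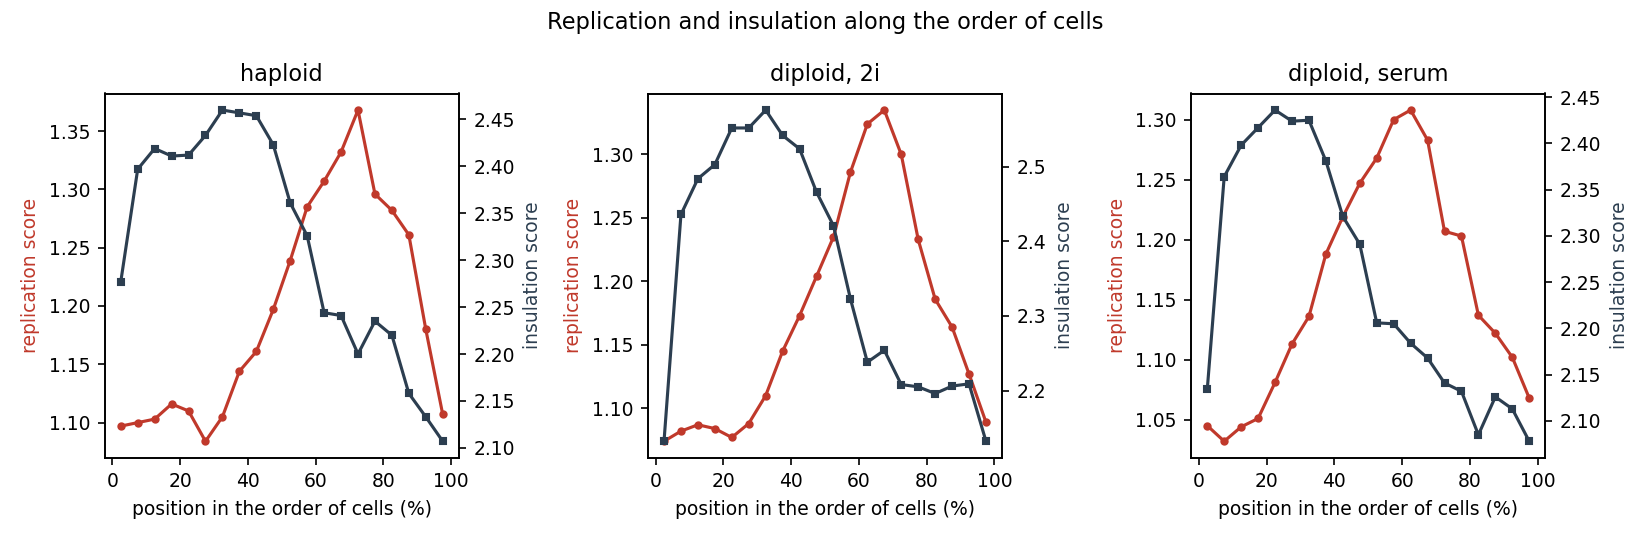
Mean replication score (red, left axis) and insulation score (dark, right axis) in 20 bins of cells against the position in the authors' order in percent, with a panel for each table and axes that do not start at 0. Insulation is highest in bins 7, 7 and 5 of the haploid, 2i and serum tables and the replication score in bins 15, 14 and 13.

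Sorting gates give a view of phase that does not rest on contacts. Per the labels, nuclei were sorted on Hoechst and Geminin staining, and the diploid 2i table names 4 gates, read here as G1, early S, mid S and late S/G2. Most cells of the early gates fell into the matching group, namely 221 of 280 G1-gate cells in G1 (78.9%, exact 95% interval 73.7 to 83.6) and 285 of 303 early-S-gate cells in early-S (94.1%, 90.8 to 96.4). Of 262 mid-S-gate cells, 64.9% (58.8 to 70.7) were in late-S/G2 and 31.7% in early-S. Of 326 late gate cells, 77.6% (72.7 to 82.0) were in late-S/G2, 7.06% in pre-M and 5.21% in post-M. Median positions in the authors' order, in percent of the cells, were 13.2, 44.9, 70.2 and 87.2. In haploid cells of the 2i G1 gate, 51.3% (45.2 to 57.4) were in G1 and 46.1% in early-S.

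From the G1 to the late gate, the short-range share was 58.9%, 72.1%, 78.7% and 79.1%. The replication score was 1.08, 1.195, 1.28 and 1.13, lower in the late gate than in the early-S gate, whereas by group, over sets of libraries that differ, it was 1.08, 1.19 and 1.225 in G1, early-S and late-S/G2. Insulation was 2.46, 2.51, 2.21 and 2.15, so the fall lay between the early-S and mid-S gates. The 2 libraries with at least 10 cells spanned 2.507 to 2.509 in the early-S gate and 2.202 to 2.221 in the mid-S gate. No test was made with 2 libraries per gate, and each gate came from its own libraries except in 1 library with 5 or 6 cells of each. Within cells that the authors placed in early-S, insulation depended on the gate. It was 2.56 and 2.54 in the libraries of the G1 gate, 2.51 and 2.52 in those of the early-S gate, 2.22 and 2.24 in those of the mid-S gate, and 2.29 and 2.26 in those of the late gate (12 and 17 cells).

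**Figure D3:**
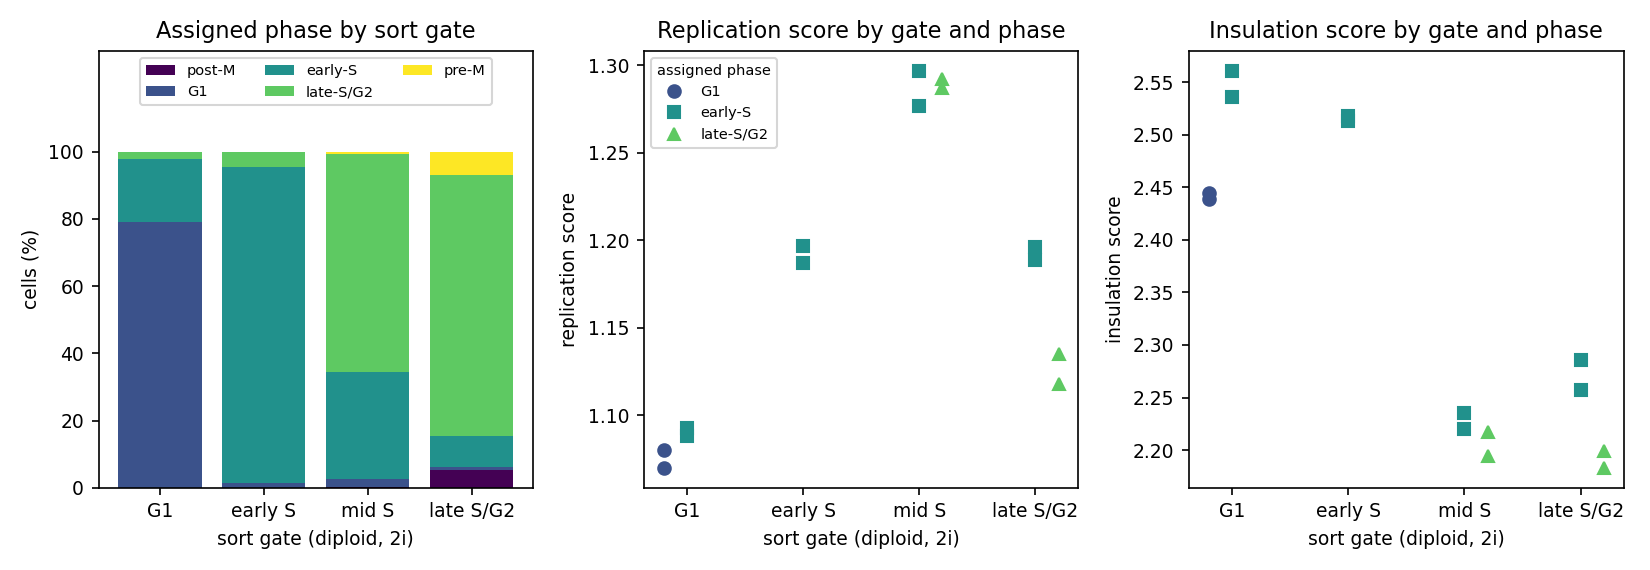
Share of diploid 2i cells in each assigned phase by sort gate (bars, percent of cells), and replication and insulation scores by gate, with a point for each library and assigned phase with at least 10 cells and symbols for the phase. Early-S cells have insulation of 2.51 and 2.52 in the early-S gate and 2.22 and 2.24 in the mid-S gate.

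Composition by phase was compared between haploid 2i libraries of the condition 2i_all, whose name gives no sort, and diploid libraries named NoSort. The groups have other limits in each table, late-S/G2 starting at a short-range share of 73.4% in haploid and 76.95% in diploid 2i cells, so differences in composition are partly set by the grouping. Early-S held 30.4% ± 2.67 (SD, n = 6) of haploid cells and 41.4% ± 3.72 (n = 5) of diploid cells (exact p = 0.00216, adjusted p = 0.0108 over 5 phases). Late-S/G2 held 55.2% ± 6.70 of haploid and 40.8% of diploid cells (exact adjusted p = 0.0271). G1, post-M and pre-M shares did not pass (exact adjusted p from 0.123 to 0.336). With the 1CDU libraries, whose name is not explained, added to the diploid side, the differences were larger (early-S 51.8%, late-S/G2 25.4%, exact adjusted p = 0.0105 each). The 1CDU libraries themselves held 6.28% ± 4.86 late-S/G2 cells against 40.8% in the NoSort libraries (4 against 5, exact adjusted p = 0.0132), with 0 of 401 cells in post-M or pre-M, which allows a share of up to 0.748% each. In serum, 5 libraries with 1CDS1 cells held 62.0% early-S and 18.6% late-S/G2 cells, and 5 with 1CDS2 cells held 26.4% and 51.1%. Diploid 1_6 and diploid 5_10 were in both sets, so their values were swapped and labels permuted among the other 6 libraries. This test cannot go below p = 0.025, and no share passed (exact p = 0.025, adjusted p = 0.0625 for each of these). Within the shared libraries, early-S held 63.6% of 11 cells against 33.3% of 12 in diploid 1_6, and 58.3% of 48 against 34.3% of 70 in diploid 5_10. These names are not explained, so the shares carry no reading as a growth difference. No phase share passed between 8 serum and 9 2i diploid libraries, with diploid 2_14 on both sides (exact adjusted p from 0.445 to 0.52).

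Haploid libraries and diploid 2i libraries differ by line and ploidy, which are not told apart. Values were averaged over G1, early-S and late-S/G2 with equal weight, in 13 haploid libraries, 4 grown with serum and 9 in 2i, and 17 diploid libraries, and 7 features with a common scale were tested. The short-range share was 2.31 percentage points lower in haploid cells (68.0% against 70.3%, permutation p = 0.0001, adjusted p = 0.00035), with the gap in G1 (54.0% ± 0.941 against 57.1% ± 1.14) and early-S (68.6% against 71.8%), and 81.5% against 82.0% in late-S/G2. The groups have other limits in each table, early-S starting at a share of 57.5% in haploid and 62.2% in diploid 2i cells, so this gap is partly set by the grouping. In cells taken whatever their phase it was 3.38 points and did not pass (permutation adjusted p = 0.180). Contacts per cell were 100894 against 182035 (permutation adjusted p = 0.00147), but in the 10 libraries holding all 3 phases the difference reversed to 6275 more in haploid cells (exact adjusted p = 0.786). Of these, the 5 haploid libraries are 4 of serum and 1 of 2i, and the 5 diploid ones 4 NoSort and 1 1CDU, so this sets mostly serum haploid against 2i diploid cells. Over all libraries, the shares without digestion (29.4% against 40.0%) and of duplicated fragment ends (1.24% against 3.58%) were lower too (permutation adjusted p = 0.00147 and 0.00028). The mitotic-band share (0.281 points higher), far distance (0.778 Mb higher) and share between chromosomes (0.984 points higher) did not pass (permutation adjusted p = 0.118, 0.142 and 0.142), except that the mitotic-band difference passed without diploid 19 (0.338 points, adjusted p = 0.0489). With haploid 2i libraries only, the far distance passed at 1.47 Mb higher in haploid cells (9 against 17, exact adjusted p = 0.0191), and the share between chromosomes turned to 0.413 points lower (exact adjusted p = 0.443). In the 10 libraries holding all 3 phases, with their other mix of media and sorts, the far distance turned to 0.764 Mb lower (exact adjusted p = 0.156). In cells of overlapping depth the short-range gap was 2.03 points lower in haploid cells, a value that no longer passed with 14 libraries left, so depth was not separated from the line here (permutation adjusted p = 0.187). No lane holds both lines, and lane differences are part of the spread between libraries that the test uses.

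For scores, whose scale may be set within each table, levels are given side by side without a test. Haploid cells had a lower cis compartment score (0.356 against 0.400) and trans compartment score (0.218 against 0.285). Insulation was 2.32 against 2.37 (2.39 against 2.48 in G1). Log2 enrichment was higher at EE (0.99 against 0.69) and LL loops (1.29 against 0.89).

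Serum and 2i differ in medium, feeders, Oct-3/4 sort and, in part of 2i, sort gate, so culture and sort are not told apart. Between 8 serum and 17 diploid 2i libraries, far contacts were shorter in serum by 2.95 Mb (24.2 against 27.2 Mb, exact p = 9.25e-07, the smallest the split allows, adjusted p = 6.47e-06). In G1 they averaged 23.4 Mb in serum and 27.9 ± 2.01 Mb in 2i (SD, n = 7 and 10), and in the 1 sequencing lane that held cells of both, 24.3 and 28.8 Mb (13 and 21 G1 cells). The mitotic-band share was 0.725 points higher in serum (exact adjusted p = 0.00865) and the short-range share 1.47 points lower (68.8% against 70.3%, exact adjusted p = 0.0130). In cells taken whatever their phase the short-range share turned to 0.350 points higher in serum (exact adjusted p = 0.974), and the mitotic-band difference of 0.0216 points did not pass. The limits of the groups differ between these tables too, G1 ending at a short-range share of 63.9% in serum and 65.3% in 2i cells. By phase the short-range share was 53.3% against 57.1% in G1 and 71.9% against 71.8% in early-S. In the shared lane the mitotic-band share in G1 was 17.3% against 14.6% and the short-range share 53.7% against 58.8%. In cells of overlapping depth the far distance passed (-3.12 Mb) and the mitotic-band and short-range differences did not (0.875 and -1.30 points). Serum cells had more contacts (273997 against 182035) and a lower share without digestion (31.6% against 40.0%, exact adjusted p = 0.0130 each). The difference in contacts no longer passed without the NoSort libraries (64500), in cells whatever their phase (66958) or of overlapping depth (11480). The library diploid 2_14 is on both sides, and without it the far distance (2.95 Mb shorter), mitotic-band share, short-range share, contacts and share without digestion still passed. The share between chromosomes did not pass (6.51% against 6.07%, exact adjusted p = 0.392), but passed without diploid 11 (0.718 points higher in serum, exact adjusted p = 0.00944). The duplicated share did not pass (exact adjusted p = 0.400).

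Scores of the serum and 2i tables are again set side by side untested. Within chromosomes the compartment score was 0.123 in serum and 0.400 in 2i, and the trans compartment score 0.0303 and 0.285. No ratio is given, as the zero of these scores is not defined. Insulation was 2.28 and 2.37, the replication score 1.15 and 1.17, and the alignment score 0.308 and 0.266. Libraries overlapped in insulation except in G1 (up to 2.376 in serum, from 2.439 in 2i).

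Within the haploid table, where scores share a scale, 4 serum and 9 2i libraries could be compared for 15 features, a comparison chosen after the data were seen. Contacts between chromosomes made up 9.26% in serum and 5.65% in 2i cells, and contacts per cell were 154988 and 65840 (exact p = 0.0014 each, the smallest this split allows, adjusted p = 0.00699). In early-S the share between chromosomes was 11.1% ± 0.350 (SD, n = 4) and 6.54% ± 0.721 (n = 9). Cis compartment scores were higher in serum (0.385 against 0.337, exact adjusted p = 0.00699), opposite to the levels of the diploid tables. Trans compartment scores were higher too (0.242 against 0.202, exact adjusted p = 0.0262), which stopped passing without haploid 17, 18, 19 or 20 (0.0391, 0.0407, 0.0387 and 0.0398 higher, exact adjusted p = 0.0511). No other feature passed. The alignment score (0.0671 higher, exact adjusted p = 0.0545) passed without haploid 1, 3, 7 or 8 (0.0710, 0.0688, 0.0794 and 0.0699). EE loop enrichment passed without haploid 3 (-0.13), and the duplicated share (0.537) and coverage deviation (0.133) passed without haploid 1. The condition name of the haploid serum libraries mentions G1/S, and part of the 2i libraries were named G1, so these groups also differ in their sort.

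**Figure D4:**
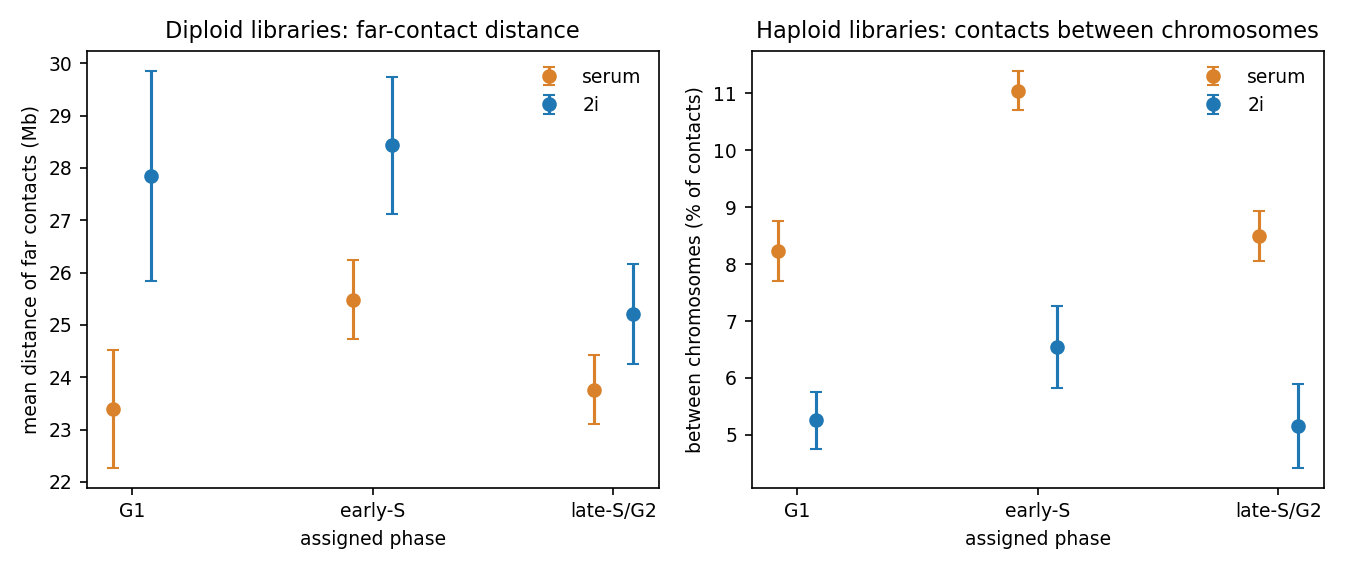
Far distance in Mb in diploid libraries and share of contacts between chromosomes in percent in haploid libraries, by assigned phase, as mean (points) and SD (bars) over serum and 2i libraries, with axes that do not start at 0. In early-S the haploid share is 11.1% in serum and 6.54% in 2i, and in G1 the diploid distance is 23.4 Mb in serum and 27.9 Mb in 2i.

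Within a phase, features were related across the cells of each library, by Spearman's rho per library. Cells are not independent replicates, so the sign of rho was tested over libraries, with 45 tests in the family. In early-S, cells with a higher replication score had lower insulation. The median rho was -0.524 over 11 haploid libraries (range -0.758 to -0.0383, below 0 in every library, permutation adjusted p = 0.0119) and -0.570 over 14 diploid 2i libraries (-0.724 to -0.132, every library, permutation adjusted p = 0.0051). In 6 serum libraries it was -0.678 (-0.794 to -0.120), where the exact test cannot go below p = 0.0312 (exact adjusted p = 0.0781). The relation was near 0 in G1 (-0.0105, 0.0648 and 0.0735) and in late-S/G2 (0.0672, 0.0985 and 0.0617), none of which passed. Short-range share and insulation were related negatively in early-S (-0.358 haploid, below 0 in 9 of 11 libraries, permutation adjusted p = 0.0391, and -0.377 in 2i, 13 of 14, permutation adjusted p = 0.0051). In G1 they were related positively (0.377 in 8 of 8 haploid libraries, exact adjusted p = 0.0391, and 0.469 in 6 of 6 diploid 2i libraries, exact adjusted p = 0.0781). Insulation rose with the cis compartment score in haploid G1 (0.179, 8 of 8, exact adjusted p = 0.0391) and in 2i early-S (0.185, 13 of 14, permutation adjusted p = 0.0051). The replication score fell with contacts per cell in haploid G1 (-0.339) and 2i late-S/G2 (-0.299), in 8 of 8 libraries each (exact adjusted p = 0.0391).

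Uneven chromosome coverage was described as in the tables by the largest deviation of any chromosome in a cell. A deviation of 1 or more was found in 260 of 2924 diploid 2i cells (8.89%, exact 95% interval 7.89 to 9.98), 77 of 1175 serum cells (6.55%, 5.21 to 8.12) and 190 of 1772 haploid cells (10.7%, 9.32 to 12.3). All of these cells had failed quality control, and the highest values in passing cells were 0.9982, 0.984 and 0.9997, so passing cells give no estimate of this share. By condition the share ran from 3.68% in haploid 2i_G1 to 16.1% in diploid 1CDU. NoSort libraries stood apart in quality, with a share without digestion of 48.2% ± 1.21 (SD, n = 5) against 35.1% to 37.0% in the other conditions of the 2i table, and with 53.0% of their cells passing.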

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

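The tests of differences between groups of libraries in their phase changes were chosen after the phase changes had been seen, and so were the tests of lane, score scale, library batch, haploid depth and G1 sort, and of serum in both lines. The depth test of the compartment score also was, replacing one set beforehand that took a ratio of scores without a defined zero. The tests of depth and position for insulation in early-S cells and of uneven coverage were set beforehand. Unless stated otherwise, intervals in parentheses in this section are the middle 95% of values from resampled libraries.

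Phase changes differed in size between groups of libraries in 10 of 40 tests (permutation of library labels, exact, two-sided). The step from early S to late S/G2 raised the short-range share by 11.7 points in haploid and 8.45 in diploid 2i libraries, a difference of 3.24 (9 against 9, exact adjusted p = 0.00617). The groups separate on this share with other limits in each table, early-S starting at 57.5% in haploid and 62.2% in diploid 2i cells, so the difference is partly set by the grouping and carries no reading as a difference of haploid cells. From G1 to early S, serum libraries moved further than 2i libraries in the diploid line (7 against 10 libraries). The short-range share rose by 18.5 against 13.2 points (difference 5.26, exact adjusted p = 0.0117), the mitotic-band share fell further (difference -1.99, exact adjusted p = 0.00617), and the share between chromosomes rose by 2.17 against 1.04 points (difference 1.13, exact adjusted p = 0.0318). Contacts per cell changed by -15475 in serum and 37894 in 2i from early S to late S/G2 (7 against 9, difference -53369, exact adjusted p = 0.0140). The 2i libraries differ in their sort, and into early S their short-range share rose by 9.87 points in the G1 gate, 12.1 in 1CDU and 16.1 in NoSort libraries. Against the 4 NoSort libraries alone, the serum difference was 2.40 points and no longer passed (exact adjusted p = 0.0808), and so did that in contacts into late S/G2 (-54248, exact adjusted p = 0.0559), while the mitotic-band share (-1.48, exact adjusted p = 0.0404) and the share between chromosomes (1.92, exact adjusted p = 0.0397) passed. Without diploid 2_14, which is on both sides, the share between chromosomes no longer passed (1.15, exact adjusted p = 0.0529).

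In haploid cells 4 serum libraries were set against 5 of 2i, where the smallest exact p is 0.00794 and the adjusted p was 0.0318 for each of these. The replication score changed by 0.157 in serum against 0.0609 in 2i into early S (difference 0.0960), and by -0.00454 against 0.0974 into late S/G2 (difference -0.102). Insulation fell less into late S/G2 (-0.156 against -0.260, difference 0.103), and the share between chromosomes fell more (-2.56 against -1.09 points, difference -1.47). Contacts per cell rose by 46685 against 3827 into early S (difference 42858). By their names these libraries also differ in sort. The 2i side was 4 libraries of 2i_G1 and 1 of 2i_all into early S, and 5 of 2i_all into late S/G2. Medium and sort are not told apart, and no explanation was tested.

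A library far from the others was found in 3 of 81 groups of 4 to 10 libraries, where chance alone gives about 1 in 20. In the step from early S to late S/G2 the alignment score rose by 0.126 in diploid 25, against 0.0270 to 0.0728 in the other 8 diploid 2i libraries. From G1 to early S, contacts per cell changed by -43287 in diploid 5_10, against 5960 to 33567 in the other serum libraries. The G1 share of diploid 1_6 was 33.3% of its 12 cells in 1CDS2, against 12.7% to 15.6% in the others.

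The cis compartment score was lower in the diploid serum table than in the diploid 2i table, by 0.277 if both share a scale. Depth is argued against, since within libraries and phases of the 2i table cells above the median depth, with 135800 more contacts on average than the others, differed from them by -0.00121 (-0.00928 to 0.00669). A lowering by serum in both lines is argued against by the haploid table, where serum was higher by 0.0487 (4 against 9 libraries, exact adjusted p = 0.00699). Sequencing lane is argued against, since each library had lanes of its own and in G1 the lowest of 10 2i libraries lay 0.197 above the highest of 7 serum libraries (range between libraries 0.0626 and 0.0108). The 1 lane with both media had a difference of 0.252 in 21 and 13 cells. Its interval of 0.2199 to 0.284 draws cells of 1 library and covers no spread between libraries. A score scale set separately in each table may account for it. The spread over cells and the change from G1 to early S, which do not depend on where zero lies, were larger in 2i by factors of 2.503 and 2.599, a ratio of 0.963 (0.752 to 1.199). A weaker compartment contrast in diploid serum cells would also scale both, so a difference of culture, in the diploid line alone or in both lines, stays open.

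Early-S cells had lower insulation in the mid-S gate than in the early-S gate, by -0.288 (83 against 281 cells). Position within early-S was held only by the short-range share, and 0.799 (0.687 to 0.888) of the difference stayed within 8 bins of it. The short-range share as the sole cause is thus argued against in these libraries. The replication score was not held. It was 1.297 and 1.277 in the mid-S-gate libraries and 1.187 and 1.197 in those of the early-S gate, so position as a whole stays open. Depth is argued against in these libraries by 0.930 (0.875 to 0.979) staying within 8 bins of contacts. Both intervals draw cells within libraries, so they leave out the spread between the libraries of a gate. The library batch of each gate cannot be told apart, because each gate has 2 libraries of at least 10 cells and the 1 library with both gates (difference -0.233, 5 against 6 cells) holds 0 early-S cells of the mid-S gate. A span of 1 standard error over cells to either side of that difference is -0.318 to -0.148. A fall of insulation that goes with S-phase progress beyond the short-range share may underlie it, as a hypothesis with batch open.

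Contacts between chromosomes made up a larger share in haploid serum than haploid 2i libraries, by 3.61 points. Depth as the whole cause is argued against, since 0.856 (0.705 to 1.06) of the difference stayed in cells of 42549 to 116137 contacts, and so is uneven chromosome coverage, with 0.881 (0.779 to 1.42) staying. The G1 sort of some 2i libraries is argued against, as 1.09 (0.941 to 1.25) of the difference stayed against the 2i_all libraries, whose name gives no sort. In G1 that side is 1 library of 17 cells, against 5 libraries in early-S and in late-S/G2. An effect of serum in both lines stays open, as the diploid difference was 0.442 points (8 against 17, exact adjusted p = 0.392). The sort of the serum libraries on G1/S, by their name, and any effect of serum culture in the haploid line alone may each contribute and were not told apart.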

How the results depend on the processing

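The alternatives with a minimum of 1 cell, without the NoSort libraries, with haploid 2i libraries only, with libraries holding the 3 phases, with the shared sequencing lane, without the library holding both media and within haploid cells, and all those for differences in phase changes between groups, were chosen after the data were seen. The other alternatives were chosen before the data were examined. Across 172 results, 922 recomputations were made. In 644 of them direction and side of the threshold stayed. In 189 direction stayed and the adjusted p no longer passed 0.05, and in 28 it newly passed. In 13 an untested value moved beyond the library spread, some in sign, and 48 others changed sign. Reversals concerned results that had not passed the threshold, except the haploid against diploid difference in contacts and the serum against 2i difference in short-range share. Below, "into early S" means the change from G1 to early S and "into late S/G2" the change from early S to late S/G2, with shares in percentage points, distances in Mb and contacts as counts. Where no cause is named, the cause was not tested.

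Medians over cells in place of means left 84 results as they were, and a minimum of 5 cells left 85. Pooling all cells left 64 results as they were, Pearson in place of Spearman left 40, the partial correlation given contacts per cell left 33, and weighting libraries equally or using only libraries whose names give no sort (2i_all and NoSort) left 5 each. Leave-one-out left 120 recomputations as they were, where a result can count more than once. The alternative limits of 1.2 and 0.8 for chromosome copy number, and the main limits of 1.3 and 0.7, were not run, since no coverage per chromosome was used here.

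With a minimum of 20 cells per library and phase, 44 phase changes no longer passed, all with their direction kept and 42 of them with every library moving the same way. Between 3 and 8 libraries remained, with adjusted p from 0.0726 to 0.316. For those 42 the loss follows from the lower number of libraries. The short-range share changed by 13.9 into early S and 11.2 into late S/G2 in haploid libraries, 11.3 into early S and 8.33 into late S/G2 in 2i libraries, and 18.3 into early S and 9.36 into late S/G2 in serum libraries. The mitotic-band share changed by -4.04 into early S and -3.52 into late S/G2 in haploid libraries, -3.70 into early S and -3.12 into late S/G2 in 2i libraries, and -6.43 into early S and -3.10 into late S/G2 in serum libraries. The contact distance changed by 2.29 into early S and -1.79 into late S/G2 in haploid libraries, -2.25 into late S/G2 in 2i libraries, and 2.898 into early S and -1.62 into late S/G2 in serum libraries. Into early S the replication score changed by 0.104 in haploid, 0.0543 in 2i and 0.147 in serum libraries. Into late S/G2 insulation changed by -0.196 in haploid, -0.137 in 2i and -0.204 in serum libraries. Into early S and late S/G2 the cis compartment score changed by 0.0886 and 0.0402 in haploid and 0.0751 and 0.0398 in 2i libraries. In serum libraries it changed by 0.0287 and 0.0195. The trans compartment score changed by 0.0845 and 0.0391 in haploid and 0.0906 and 0.0236 in 2i libraries, in the same order. The share between chromosomes changed by 2.15 into early S and -1.89 into late S/G2 in haploid libraries, 1.57 into early S and -1.45 into late S/G2 in 2i libraries, and 2.22 into early S and -1.41 into late S/G2 in serum libraries. The alignment score changed by -0.0534 into early S in haploid libraries, 0.0396 into late S/G2 in 2i libraries, and -0.0396 into early S in serum libraries. Contacts per cell changed by 25019 into early S in haploid libraries, and 30881 into late S/G2 in 2i libraries. The alignment score into late S/G2 in haploid libraries turned to 0.0106, and insulation into early S in 2i libraries turned to 0.0520.

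Cells within the central 25th to 75th percentile of contacts left between 2 and 7 libraries. Here 44 phase changes no longer passed, all with their direction kept and 36 with every library moving the same way, so that for these 36 the lower number of libraries is the cause. For the other 8 the cause was not tested, among them the trans compartment score into late S/G2 in 2i libraries. Adjusted p ran from 0.158 to 0.758. The short-range share shifted by 13.1 into early S and 11.9 into late S/G2 in haploid libraries, 11.2 into early S and 8.50 into late S/G2 in 2i libraries, and 18.5 into early S and 10.1 into late S/G2 in serum libraries. The mitotic-band share shifted by -3.94 into early S and -3.62 into late S/G2 in haploid libraries, -3.62 into early S and -3.15 into late S/G2 in 2i libraries, and -5.96 into early S and -3.15 into late S/G2 in serum libraries. The contact distance shifted by 2.48 into early S and -1.56 into late S/G2 in haploid libraries, -1.99 into late S/G2 in 2i libraries, and 2.08 into early S and -2.64 into late S/G2 in serum libraries. Into early S the replication score shifted by 0.0865 in haploid, 0.0498 in 2i and 0.128 in serum libraries. Into late S/G2 insulation shifted by -0.232 in haploid, -0.154 in 2i and -0.245 in serum libraries. Into early S and late S/G2 the cis compartment score shifted by 0.0897 and 0.0502 in haploid and 0.0824 and 0.0364 in 2i libraries. In serum libraries it shifted by 0.0365 and 0.0251. The trans compartment score shifted by 0.0834 and 0.0390 in haploid and 0.0957 and 0.00851 in 2i libraries, in the same order. The share between chromosomes shifted by 1.94 into early S and -1.97 into late S/G2 in haploid libraries, 1.79 into early S and -1.35 into late S/G2 in 2i libraries, and 2.17 into early S and -2.13 into late S/G2 in serum libraries. The alignment score shifted by -0.0580 into early S in haploid libraries, 0.0333 into late S/G2 in 2i libraries, and -0.0358 into early S in serum libraries. Contacts per cell shifted by 1612 into early S in haploid libraries, and 3473 into late S/G2 in 2i libraries. Contacts per cell are narrowed by this selection itself. Sign changes were found for insulation into early S (0.00687 in haploid and 0.0643 in 2i libraries), for the alignment score into late S/G2 in haploid libraries (0.0158), and for contacts per cell (-675 into early S in 2i and 21020 into late S/G2 in serum libraries). The share of G1-gate cells assigned to G1 moved to 84.1% and that of mid-S-gate cells assigned to late S/G2 to 58.2%. Cells with a coverage deviation of at least 1 fell to 5.61% in the 2i table, 2.38% in the serum table and 6.77% in the haploid table.

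Without the NoSort libraries, 5 or 6 libraries of the diploid 2i table remained and 15 phase changes no longer passed, 14 of them with every library moving the same way. The short-range share moved by 11.3 into early S and 7.58 into late S/G2. The mitotic-band share moved by -3.70 into early S and -2.54 into late S/G2. The contact distance moved by -2.79 and insulation by -0.112 into late S/G2, and the replication score by 0.0543 into early S. The cis compartment score moved by 0.0751 into early S and 0.0474 into late S/G2. The trans compartment score moved by 0.0906 into early S and 0.0467 into late S/G2. The share between chromosomes moved by 1.57 into early S and -1.32 into late S/G2. The alignment score moved by 0.0664 and contacts per cell by 37191 into late S/G2. Insulation into early S turned to 0.0520. In the serum against 2i comparison the difference in contacts fell to 64500 and no longer passed, and the difference in duplicated share turned to 0.384.

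With haploid 2i libraries only, 5 libraries remained and 16 phase changes no longer passed, 14 of them with every library moving the same way. An exact test on 5 libraries cannot go below p = 0.0625. The short-range share came to 12.5 into early S and 12.6 into late S/G2. The mitotic-band share came to -4.18 into early S and -3.89 into late S/G2. The contact distance came to 3.54 into early S and -1.52 into late S/G2. The replication score came to 0.0609 into early S. Insulation came to -0.260 into late S/G2. The cis compartment score came to 0.0770 into early S and 0.0451 into late S/G2. The trans compartment score came to 0.0912 into early S and 0.0502 into late S/G2. The share between chromosomes came to 1.39 into early S and -1.09 into late S/G2. The alignment score came to -0.0807 and contacts per cell to 3827 into early S. Insulation into early S turned to 0.0518 and the alignment score into late S/G2 to 0.00223. Against diploid 2i libraries the contact distance newly passed at 1.47 Mb higher in haploid 2i libraries, and the difference in share between chromosomes turned to -0.413.

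Leaving out 1 serum library at a time leaves 6, and an exact test on 6 libraries cannot go below p = 0.0312, which the correction raised to between 0.0507 and 0.0527. Each of the changes below had passed in the serum table, and each stopped passing by construction whichever library was left out. The short-range share ranged from 18.2 to 18.9 into early S and from 9.09 to 9.86 into late S/G2. The mitotic-band share ranged from -6.17 to -5.89 into early S and from -3.23 to -3.03 into late S/G2. The contact distance ranged from 2.01 to 2.45 into early S and from -2.09 to -1.50 into late S/G2. The replication score ranged from 0.134 to 0.146 into early S. Insulation ranged from -0.211 to -0.179 into late S/G2. The cis compartment score ranged from 0.0268 to 0.0297 into early S and from 0.0190 to 0.0205 into late S/G2. The share between chromosomes ranged from 2.06 to 2.36 into early S and from -1.66 to -1.25 into late S/G2. The alignment score ranged from -0.0371 to -0.0308 into early S.

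In the haploid table, leave-one-out values of the contact distance into late S/G2 ran from -1.67 to -1.22, and those of contacts per cell into early S from 16725 to 26370. The first stopped passing on leaving out any of 8 libraries, haploid 17, 18, 19, 20, 3, 6, 7 and 8, and the other on leaving out any of 7, haploid 12, 13, 17, 18, 19, 20 and 7. Changes that newly passed without 1 library were the replication score into late S/G2 (from 0.0398 to 0.0650, passing without haploid 19) and contacts into late S/G2 (from 9394 to 18494, passing without haploid 18) in haploid libraries, and contacts into early S in 2i libraries (from 10259 to 16780, passing without diploid 19). Ranges that included a change of sign were insulation into early S in haploid (from -0.0226 to 0.00561) and 2i libraries (from -0.0161 to 0.0102), the alignment score into late S/G2 in haploid libraries (from -0.0109 to 0.00376) and the replication score into late S/G2 in 2i libraries (from -0.00600 to 0.0195).

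Leaving out 1 library from the group comparisons gave 0.224 to 0.338 for the haploid minus diploid mitotic-band share, newly passing without diploid 19. For the serum minus 2i share between chromosomes in diploid cells the range was 0.321 to 0.718, newly passing without diploid 11. Within haploid cells the serum minus 2i trans compartment score ran from 0.0353 to 0.0424 and stopped passing without haploid 17, 18, 19 or 20. The alignment score ran from 0.0598 to 0.0794 and newly passed without haploid 1, 3, 7 or 8. EE loop enrichment ran from -0.133 to -0.0956 on the log2 scale and newly passed without haploid 3. The duplicated share ran from 0.276 to 0.537 and the coverage deviation from 0.0972 to 0.133, each newly passing without haploid 1.

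Remaining phase changes differed in single alternatives. With medians, the contact distance came to -1.002 into late S/G2 in haploid libraries and 1.53 into early S in serum libraries, the cis compartment score to 0.0151 into late S/G2 in serum libraries, none of them past the threshold, and insulation into early S in 2i libraries turned to 0.0165. With a minimum of 5 cells, contacts into early S in haploid libraries came to 16599 and no longer passed, the trans compartment score into early S in serum libraries newly passed at 0.0182, and sign changes gave 0.00772 for insulation into early S and 0.00603 for the alignment score into late S/G2, both in haploid libraries. With a minimum of 1 cell, contacts into early S in haploid libraries (26351) and the share between chromosomes into early S in 2i libraries (0.696) no longer passed. Newly past were the replication score into late S/G2 in haploid (0.0884) and 2i libraries (0.0559), contacts into late S/G2 in haploid libraries (24286) and the trans compartment score into early S in serum libraries (0.0182), and the alignment score into late S/G2 in haploid libraries turned to 0.0429. With all cells pooled, values into late S/G2 moved to -2.63 Mb for the contact distance, -2.86 for the share between chromosomes and -17407 for contacts in the haploid table, and to -2.12, 62870 and, for the short-range share, 10.6 in the 2i table. The haploid value for contacts thereby changed sign, from 13524.

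In the haploid against diploid comparison, cells of overlapping depth gave -2.03 for the short-range share, -3376 for contacts and -2.02 for the duplicated share, all no longer past the threshold, and -0.0339 for the mitotic-band share. Contacts are narrowed by that selection itself. Cells taken whatever their phase gave -3.38 for the short-range share, no longer past the threshold. With medians the mitotic-band share newly passed at 0.348. Libraries holding the 3 phases reversed the contact distance to -0.764 Mb and contacts to 6275, with a haploid side of 4 serum and 1 2i libraries and a diploid side of 4 NoSort and 1 1CDU. With the replicate block, 5 pairs of libraries sharing a number gave -2.13 for the short-range share, -50818 for contacts, -6.51 for the undigested share and -1.35 for the duplicated share, none past the threshold because 5 pairs cannot go below p = 0.0625 in an exact test. Correlations of feature profiles between libraries with the same number ran from -0.462 to 0.774, and in 0 of 5 cases was the library of the same number the best match, so no pairing by number was seen.

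For serum against 2i, cells of overlapping depth gave -1.30 for the short-range share, 0.875 for the mitotic-band share and 11480 for contacts, none past the threshold. Cells taken whatever their phase gave 0.350, 0.0216 and 66958, and the short-range share changed sign. Libraries holding the 3 phases gave -1.85 for the duplicated share, which newly passed. Cells of the lane shared by both media gave -4.64 Mb for the contact distance and 0.770 for the duplicated share, the latter a change of sign. Within haploid cells, libraries holding the 3 phases gave 0.680 Mb for the contact distance, a change of sign, and 0.0426 and 0.0228 for the cis and trans compartment scores, 4.43 for the share between chromosomes and 110428 for contacts, no longer past the threshold. That set is 4 serum libraries against 1 of 2i, where no exact p below 0.2 is possible, so the loss is fixed by the design and the values rest on haploid 7 alone for 2i. Cells whatever their phase gave 0.0359 for the trans compartment score, no longer past the threshold, and 0.00376 for insulation, a change of sign.

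Differences in phase changes between groups were recomputed with other sets of libraries. With haploid 2i libraries only, haploid minus diploid 2i turned to -0.708 for the short-range share and -9670 for contacts into early S and to 0.336 for the share between chromosomes into late S/G2, none of which had passed. Against NoSort libraries only, serum minus 2i fell to 2.40 for the short-range share into early S and came to -54248 for contacts into late S/G2, both no longer past the threshold, and the contact distance into early S newly passed at 4.38. Changes of sign there were -0.0373 for the short-range share, 0.429 for the mitotic-band share and 0.0693 for the share between chromosomes, all into late S/G2. Without the library holding both media, the share between chromosomes into early S came to 1.15 and no longer passed, and contacts into early S turned to -3456.

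For relations within a phase, a minimum of 40 cells left between 2 and 9 libraries. Replication score and insulation in early S kept their sign at -0.621 in haploid and -0.606 in 2i libraries, and short-range share and insulation at -0.488 and -0.474, without passing. In haploid G1 cells the replication score with contacts gave -0.456, the short-range share with insulation 0.260 and insulation with the cis compartment score 0.221. In 2i libraries insulation with the cis compartment score in early S gave 0.197 and the replication score with contacts in late S/G2 gave -0.287. Signs changed for replication score with insulation in haploid G1 (0.0356), insulation with compartment score in haploid early S (-0.132), and replication score with compartment score in 2i G1 (0.124) and early S (-0.0457) and with contacts in 2i early S (0.0229). With Pearson, the haploid G1 relation of replication score and contacts no longer passed (-0.311), and signs changed for replication score with insulation in haploid G1 (0.0590), with compartment score in 2i G1 (0.0331), and with contacts in early S of 2i (0.0302) and serum libraries (-0.0623). The partial correlation given contacts gave 0.00658 for replication score with insulation in haploid G1 and -6.33e-05 for insulation with compartment score in haploid late S/G2, both changes of sign, and replication score with compartment score in 2i late S/G2 newly passed at -0.127.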

Other observations

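The tests on library batch and the added minimum of 1 cell were chosen after the result was seen. In early-S cells of the same library, insulation fell as the replication score rose (median rho -0.524 in 11 haploid, -0.570 in 14 diploid 2i and -0.678 in 6 serum libraries, with no library above 0), while in G1 and late-S/G2 the medians lay between -0.0105 and 0.0985. With at least 40 cells per library the early-S values were -0.621 in 4 haploid and -0.606 in 9 diploid 2i libraries, neither past the threshold at those numbers. Sorted cells of the authors' early-S group had insulation of 2.51 and 2.52 in the early-S gate and 2.22 and 2.24 in the mid-S gate, of which 0.799 stayed within bins of the short-range share. Early-S cells of the late gate had replication scores of 1.196 and 1.189, like the 1.187 and 1.197 of the early-S gate, but insulation of 2.29 and 2.26 (12 and 17 cells). In these libraries the replication score alone does not account for insulation across gates. Along the 2i order, like scores flanked the peak (1.173 in bin 9, 1.186 in bin 17) at insulation of 2.524 and 2.196. Equal scores thus do not match S-phase progress, which stays open with the libraries of each gate.

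The sequencing lane with cells of both media sets both side by side. In it 13 serum and 21 2i G1 cells had cis compartment scores of 0.0996 and 0.351, insulation of 2.33 and 2.46, and 262267 and 143384 contacts. The 4 gates were also present together in 1 library with 5 or 6 cells each, where insulation was 2.52, 2.45, 2.22 and 2.23 and the replication score 1.09, 1.19, 1.32 and 1.15 from the G1 to the late gate.

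Cells that failed quality control were mostly shallow in diploid cells. Of 932 failing diploid 2i cells, 659 had fewer contacts than any passing cell and 7 more than any passing cell, with a highest value of 2484307. In serum, 280 of 316 lay below and 8 above, and in haploid cells 250 of 525 lay below and 1 above.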
